A study of Homo sapiens with 6 samples.

How the data were processed

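RNA sequencing was done on 6 libraries of cells labelled as M14, an established human melanoma cell line. The cells had been grown without attachment as floating spheres (melanospheres). The spheres were broken up mechanically and stained with an antibody against CD20, the B-cell surface antigen encoded by MS4A1. Flow sorting then gave 3 CD20-positive and 3 CD20-negative fractions. Per the labels' protocols, RNA was isolated on RNeasy columns, polyadenylated RNA was made into libraries with an Illumina TruSeq kit, and sequencing was done on an Illumina NovaSeq by a service provider. The labels number the replicates 1 to 3 in each group and do not say that these came from separate cultures, so p-values measure the spread between these samples, which may be technical.

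The deposited table holds 1 value for each of 58395 Ensembl genes in each library. Its header gives no unit, and the unit was taken from the values: the deposited values are FPKM (fragments per kilobase of exon, relative to library size), computed by the authors with a library size of their own. Each value multiplied by the exon length of its gene in GENCODE release 29 gave whole multiples of one step per library for 98.1 to 98.6% of the low values (up to 20 reads, tolerance 0.02 reads). The step implies a library size that was 0.864 to 1.10 times the recovered fragment total and 0.993 to 1.04 times a size corrected by trimmed-mean (TMM) factors, so the deposited values are already scaled between libraries. Per the submitters' processing notes, HISAT2, featureCounts 1.5.0 and DESeq2 were used with the GRCh38 (hg38) build. Their settings, including whether strand was used in counting, are not given in the sources used here. Of the table's identifiers, 58275 matched GENCODE release 29 and 120 did not, which held 0.0154% of the summed FPKM. Gene types and positions were taken from that annotation, and gene symbols from a newer list of gene names where it held the gene.

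The recovered fragments came to 15651164 to 17915939 per library. Shares of fragments were computed from them. Genes with a mean of at least 10 FPKM over the 6 libraries were tested (4503 genes), on log2(FPKM + 1), with limma 3.58.1 in R (trend and robust prior, no replicate block), CD20-positive minus CD20-negative, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. The filter of 10 was fixed before the unit was known, as were the groups, the tests, the gene lists and the rule for named genes, all before the data were examined. The rule took MS4A1, the 10 protein-coding genes with the strongest increase and the 10 with the strongest decrease among those past the threshold with a mean of at least 50 FPKM and no overlap between groups, and up to 3 members of each list with the smallest p. Where no gene qualified in a direction, it took the 5 with the smallest p, which had missed the threshold. The rule was applied a second time to the paired fit. Genes outside mitochondrial and ribosomal protein genes that followed in that ranking were chosen after their values were seen.

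Whether the replicate numbers pair the samples was checked from the deviations of each library from its group mean across the tested genes. The correlations between same-numbered libraries were 0.73, 0.25 and 0.65 for replicates 1, 2 and 3, each over 0.1, so the numbers were taken as pairing the samples. The CD20-negative library of replicate 2 correlated better with the CD20-positive library of replicate 3 (0.59), and that of replicate 3 correlated with the CD20-positive library of replicate 2 at 0.54, so these values set replicate 1 apart but do not tell how replicates 2 and 3 pair. A block with replicates 2 and 3 swapped was not run, so the paired calls hold for the labelled numbers only. A limma fit with the replicate number as a block (the paired fit) was run beside the fit without it. Unless stated, counts of called genes in a list are from the paired fit and camera values from the fit without the block. At the filter of 10 FPKM the fit without the block called 0 genes in each tested list over all genes tested. It called 1 gene in total, so other named genes passed at that filter in the paired fit only or not at all. The paired fit has 2 residual degrees of freedom per gene, and 93.4% of the genes were given an infinite prior, that is, a spread taken from all genes at a similar level and none from the gene itself.

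Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 20 of 35 lists that had at least 5 tested members, and again with an estimated correlation and with fry. Single values were compared with two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3. Alternatives covered the pseudocount, the filter, 5 other scalings, the prior, library weights, the block, voom on the recovered fragments, stricter thresholds and left-out libraries. The count tests of edgeR and DESeq2 were not run, since the deposited unit is FPKM.

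The steps were tested on simulated data of 4503 genes before use. The fit without the block recovered 4.48% of genes changed by 0.5 on the log2 scale, 47.8% of those changed by 1 and 87.9% of those changed by 2, and 2 of its 95 calls were false. The paired fit recovered 8.96%, 68.7% and 95.5%, and 3 of its 118 calls were false. Genes were drawn independently in the simulation, which real genes are not. For the paired fit the simulated spreads were the real estimates on 2 degrees of freedom, shuffled over genes. They vary between genes, whereas the infinite prior of the real paired fit gives genes at a similar level the same spread. The simulated share of false calls therefore does not bear on the real paired calls.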

Results

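The data were 6 transcriptome libraries from melanospheres of cells labelled as M14, 3 sorted as CD20-positive and 3 as CD20-negative. The single comparison asked which transcripts mark the sorted CD20-positive fraction. The deposited FPKM values corresponded to 16666538 to 17915939 fragments per CD20-negative library and 15651164 to 17479726 per CD20-positive library. The number of genes at 1 FPKM or more was 13104 ± 326 in CD20-negative and 13165 ± 434 in CD20-positive libraries (exact permutation test, p = 0.8).

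MS4A1, which encodes CD20 (ENSG00000156738, GRCh38 chromosome 11, 60455752 to 60470760), was higher in each CD20-positive library than in any CD20-negative library, at a low level in both. It measured 1.16 ± 0.170 FPKM in CD20-positive and 0.297 ± 0.0940 FPKM in CD20-negative cells (SD, n = 3), a 3.91-fold ratio (exact permutation test, p = 0.1, the smallest that 3 against 3 can give). The CD20-positive libraries held 91, 75 and 98 MS4A1 fragments and the CD20-negative libraries 21, 23 and 39. Its mean lay under the filter, and in the limma fit without a filter its log2 change of 0.74 ± 0.13 (SE) did not pass the threshold (adjusted p = 0.536, and 0.396 with the replicate block). CD37, a tetraspanin of B cells with the highest mean on the B-lineage list, chosen after its values were seen, measured 2.65 ± 1.20 FPKM in CD20-positive and 3.10 ± 1.24 FPKM in CD20-negative cells (SD, n = 3, exact permutation test, p = 0.5). Of the 23 genes on that list 2 reached a mean of 1 FPKM and 0 a mean of 10, and the median of their means was 0.0587 FPKM.

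**Figure D1:**
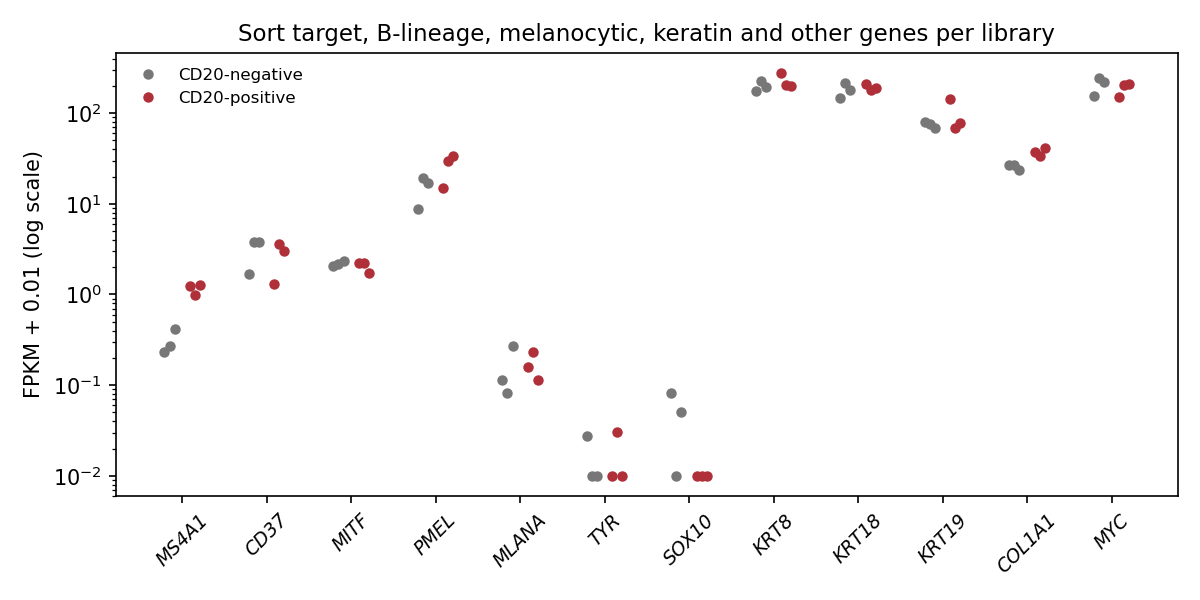
FPKM (plus 0.01, log scale) of MS4A1, CD37 and melanocytic, keratin and other genes in each library, with CD20-negative libraries in grey and CD20-positive libraries in red, and 1 point per library. MS4A1 lay between 0.966 and 1.28 FPKM in CD20-positive and between 0.225 and 0.403 FPKM in CD20-negative libraries, and SOX10, TYR and MLANA lay far below KRT8, KRT18 and KRT19 in both groups.

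The CD20-positive libraries held more mitochondrially encoded RNA and less RNA of cytosolic ribosomal protein genes. Mitochondrial genes took 16.6% ± 4.39 of the fragments in CD20-positive and 5.01% ± 0.739 in CD20-negative cells (SD, n = 3; exact permutation test, p = 0.1). The ratio within a pair was 4.85, 2.08 and 3.43. Ribosomal protein genes took 3.30% ± 0.806 against 6.71% ± 0.139 (exact permutation test, p = 0.1). In both cases the groups did not overlap, which also puts the 3 pairs in the same direction.

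**Figure D2:**
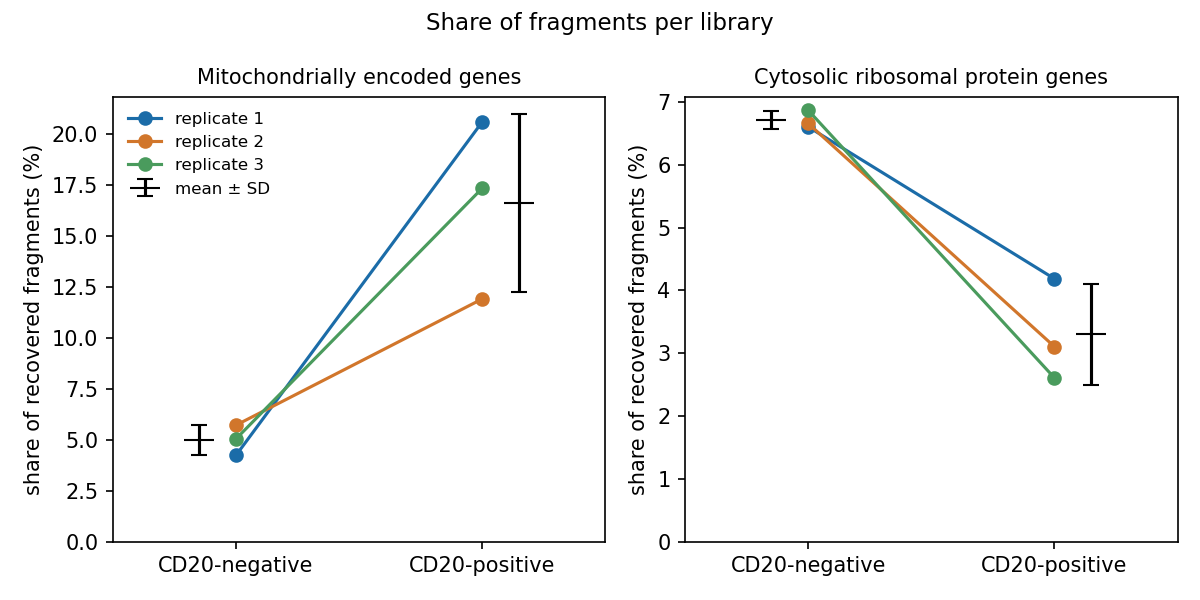
Share of recovered fragments (percent) in each library for mitochondrially encoded genes (left) and cytosolic ribosomal protein genes (right), with lines joining libraries of the same replicate number and black bars giving mean ± SD (n = 3). The mitochondrial share lay between 4.25 and 5.73% in CD20-negative and between 11.9 and 20.6% in CD20-positive libraries.

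Across genes, the fit without the block called 1 of 4503 genes, the mitochondrial glutamate tRNA gene MT-TE (log2 change 1.94 ± 0.14 SE, adjusted p = 0.00702), and 610 genes had an unadjusted p under 0.05. This count was 0 with no filter, with voom, and when the library of replicate 2 or 3 was left out of either group. It was 792 without CD20-positive replicate 1. The paired fit called 954 genes, 447 higher and 507 lower in CD20-positive cells. Of these, 896 moved the same way in the 3 pairs, which selection by a paired test favours, and 458 had no overlap between groups. Among all tested genes 49.4% moved the same way in the 3 pairs, where chance gives 25% on average over splits. No overlap was seen in 19.6%, where chance gives 10% on average. Genes vary together, so 1 split can lie far from these averages. The paired count rests on a spread shared between genes: with each gene's own spread from 2 degrees of freedom it was 0, with 606 genes at an unadjusted p under 0.05, and without both libraries of replicate 3 it was 64. Scaling each library to its FPKM total, which moved the median change of all tested genes from -0.01 to -0.50, gave 51 higher and 2401 lower genes in the paired fit, and scaling to the recovered fragment total (median -0.18) gave 212 higher and 1231 lower. The FPKM total was 416406 ± 88293 in CD20-positive and 286569 ± 9178 in CD20-negative libraries (SD, n = 3). It includes the mitochondrial genes (MT-CO1 at 29370 against 6763 FPKM), so their rise lowers every other gene under this scaling.

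The 13 mitochondrially encoded genes, which specify subunits of the respiratory chain and ATP synthase, rose in the paired fit, 13 of 13, over all genes tested and adjusted over the list alone; without the block 0 passed over all genes and 13 adjusted over the list alone. With the filter at a mean of 1 FPKM the paired fit called 9 of the 13. Their median log2 change was 1.82 (camera, adjusted p = 5.4e-20; adjusted p = 0.298 with an estimated correlation). MT-ATP8 showed the strongest rise (2.39 ± 0.29 SE in the paired fit, adjusted p = 5.8e-14), from 210 ± 34.3 to 1220 ± 642 FPKM. Without the block its SE was 0.43 (limma, adjusted p = 0.109). Paired SEs and p-values rest, for 93.4% of genes, on a spread taken from other genes. MT-CO1, a subunit of cytochrome c oxidase (mitochondrial genome, 5904 to 7445), went from 6763 ± 742 to 29370 ± 12288 FPKM (paired adjusted p = 0.0108). Under quantile normalisation the list's median was 0.13, and MT-ND4 and MT-CO3 turned to -0.07 and -0.10; that step gives each rank the same value in every library, so it takes away a change of genes that hold the top ranks, as most of these do, whatever its origin. Nuclear copies of mitochondrial genes share sequence with them, so reads can be split between both kinds, and neighbouring tRNA genes and MT-ND6 lie where the counting's use of strand matters.

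Cytosolic ribosomal protein genes fell, 36 of 39 in the paired fit (38 adjusted over the list alone) and 0 without the block (35 adjusted over the list alone), with a median log2 change of -0.84, and of -0.346, -1.03 and -1.21 in pairs 1, 2 and 3 (camera, adjusted p = 5.5e-25; adjusted p = 0.387 with an estimated correlation). With the filter at 1 FPKM the paired fit called 19 of the 39 (38 adjusted over the list alone). RPL38 (GRCh38 chromosome 17, 74203582 to 74210655) went from 150 ± 8.95 to 56.7 ± 18.5 FPKM, a log2 change of -1.44 ± 0.19 SE (paired adjusted p = 2.5e-12). RPL39, RPS12 and RPS27 changed by -1.36, -1.35 and -1.28. Processed pseudogenes share sequence with these genes and leave their single values uncertain. Nuclear-encoded subunits of oxidative phosphorylation also fell, 26 of 37, with 1 higher and 10 not called (median -0.55; camera, adjusted p = 3.0e-07; adjusted p = 0.497 with an estimated correlation). After a correction for transcript length and GC content, 17 of the 37 were lower and the median was -0.37 (SD of the members 0.31, and 0.35 before), and with the filter at 1 FPKM 16 of 43 were lower. COX7C changed by -0.996 and ATP5F1E by -1.22, whereas the mitochondrially encoded subunits of the same complexes had risen. TOMM7, part of the mitochondrial import pore, changed by -1.18.

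Extracellular matrix genes rose, 14 of 17 in the paired fit (16 adjusted over the list alone) and 0 without the block (12 adjusted over the list alone), with a median of 0.57 (camera, adjusted p = 2.6e-10; adjusted p = 0.142 with an estimated correlation). The median was 0.075 under scaling to the FPKM total, and 8 of 19 were called in the paired fit with the filter at 1 FPKM. The fibrillar collagen chain COL5A1 went from 49.2 ± 6.65 to 96.3 ± 14.3 FPKM (log2 change 0.95 ± 0.18 SE, paired adjusted p = 3.75e-06), and COL4A2 and FN1 changed by 0.75 and 1.07. LOXL2, a lysyl oxidase that crosslinks matrix (GRCh38 chromosome 8, 23297189 to 23425328), rose in the paired fit from 31.2 ± 7.97 to 73.5 ± 27.1 FPKM (1.17 ± 0.17 SE, adjusted p = 5.1e-10). It was one of 4 genes of 10 called on the list of the undifferentiated invasive melanoma state (camera, adjusted p = 0.0376; adjusted p = 0.387 with an estimated correlation). The list for the epithelial-mesenchymal transition had 5 of 12 called, each higher, among them the integrin ITGA5 at 0.83 (camera, adjusted p = 0.00349, and 0.42 with an estimated correlation). That list also holds FN1, and it shares COL5A1 with the matrix list, so these lists are not separate results. AGRN and COL7A1, chosen after their values were seen, changed by 0.86 and 0.83 in the paired fit, and NOTCH3, which the rule took from the list of WNT, NOTCH and Hedgehog targets, by 0.79.

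Genes of the G2 and M phases rose in part, 13 of 27 in the paired fit with 14 not called, a median of 0.37, and of 0.136, 0.727 and 0.455 in pairs 1, 2 and 3 (camera, adjusted p = 1.7e-06; adjusted p = 0.387 with an estimated correlation), a sign that turned to -0.13 under scaling to the FPKM total and stood at 0.37 above the median of all genes there. The mitotic ubiquitin enzyme UBE2C went from 19.3 ± 4.47 to 59.4 ± 16.2 FPKM (1.56) and the mitotic kinase AURKB from 13.5 ± 1.82 to 34.6 ± 8.43 FPKM (1.27). S phase genes had 1 of 24 called (camera, adjusted p = 0.424). The hypoxia response list had 8 of 13 higher (median 0.59, and 0.11 under scaling to the FPKM total; 8 of 25 with a median of 0.29 at the filter of 1 FPKM; camera, adjusted p = 0.00202; adjusted p = 0.45 with an estimated correlation), led by ANGPTL4, a secreted lipase inhibitor, from 9.88 ± 0.276 to 24.9 ± 2.94 FPKM (1.24). Glycolysis genes had 2 of 17 higher (camera, adjusted p = 0.424). The list of reported melanoma stem-like markers had 2 of 5 higher, MCAM at 0.49 and EPHA2 at 0.46, which turned to -0.0038 and -0.016 under scaling to the FPKM total (camera, adjusted p = 0.0236; adjusted p = 0.298 with an estimated correlation), and cholesterol synthesis genes 4 of 22 (camera, adjusted p = 0.0236; adjusted p = 0.298 with an estimated correlation). With the replicate block these last lists no longer passed (adjusted p = 0.11 and 0.113), and with the filter at 1 FPKM the paired fit called 0 of 11 and 1 of 25 of their genes. Under scaling to the FPKM total the medians of the stem-like, cholesterol synthesis, invasive state and epithelial-mesenchymal transition lists also turned, to -0.17, -0.35, -0.18 and -0.21.

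**Figure D3:**
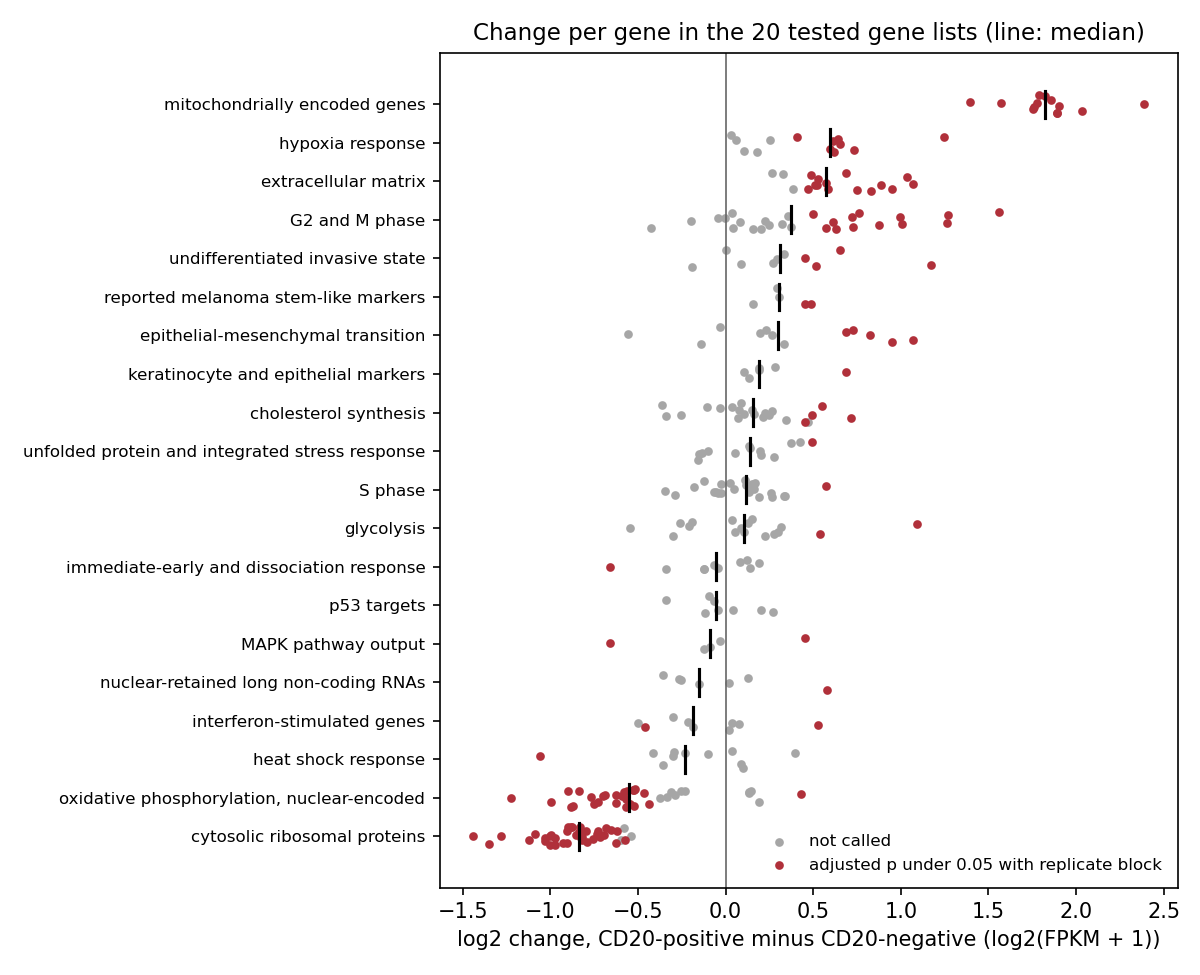
Log2 change (CD20-positive minus CD20-negative, log2(FPKM + 1)) of each tested gene in the 20 lists, 1 point per gene, red where the adjusted p of the paired fit was under 0.05, with a black line at the list's median. The mitochondrially encoded genes lay at a median of 1.82 and the cytosolic ribosomal protein genes at -0.84.

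In total 10 of the 20 lists passed camera with the preset correlation, 8 higher and 2 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.142). Fry called 3, the matrix, stem-like and mitochondrially encoded lists, and 0 with the replicate block (smallest adjusted p = 0.0924). With the block, camera called 8 lists at the preset and 0 at the estimated correlation (smallest adjusted p = 0.476). Among the 773 genes with a mean of at least 50 FPKM, the fit without the block called 43. These 43 were also called in the paired fit, and included 13 mitochondrially encoded protein genes that were higher and 11 ribosomal protein genes that were lower.

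Most melanocytic genes were low in both groups. Of the genes in this paragraph, those other than PMEL, CDK2 and KRT17 were chosen after their values were seen. SOX10, MLANA and TYR did not exceed 0.0717, 0.262 and 0.0207 FPKM in any library, and 7 of the 21 genes on the list reached a mean of 1 FPKM. MITF, a transcription factor of the lineage, measured 2.04 ± 0.279 FPKM in CD20-positive and 2.19 ± 0.138 in CD20-negative cells (exact permutation test, p = 0.6). PMEL, a melanosome protein, measured 26.1 ± 9.96 FPKM in CD20-positive and 14.96 ± 5.51 in CD20-negative cells (log2 change 0.75, adjusted p = 0.423, and 2.7e-05 in the paired fit). Its span (GRCh38 chromosome 12, 55954105 to 55973317) contains that of CDK2 (55966769 to 55972784), also on the melanocytic list. CDK2 measured 38.0 ± 3.39 against 30.6 ± 5.14 FPKM. Whether the counting used strand is not known, so the PMEL value and its change are uncertain. The keratin genes KRT8 and KRT18 measured 227 ± 43.1 and 193 ± 14.6 FPKM in CD20-positive against 198 ± 26.7 and 181 ± 35.5 FPKM in CD20-negative cells, with no call in either fit, whereas KRT17, 1 of the 6 tested genes on the keratinocyte and epithelial list, was called higher in the paired fit (42.6 ± 22.7 against 25.5 ± 12.8 FPKM, log2 change 0.69, adjusted p = 0.000368, and 0.6 without the block).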

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

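The voom fits, scaling to the recovered fragment total, the filter of 1 FPKM, leaving out both libraries of a replicate, each setting within the paired fit other than the block itself, the other scalings and the filter in the list tests, and the correction for length and GC content were chosen after seeing the data; the other settings were planned, and edgeR and DESeq2 were not run. Without the block, the count of 1 gene (1 higher, 0 lower) moved to 954 (447 higher, 507 lower) with the replicate block, 43 (26 and 17) at a mean of at least 50 FPKM, 15 (10 and 5) with quantile normalisation, 1834 (31 and 1803) with scaling to the FPKM total, 0 (0 higher) with no filter or with voom, and 1682 (723 and 959) with library quality weights, whose estimate did not converge. Leaving out libraries gave 0 to 1632 genes (0 to 650 higher, 0 to 982 lower), among them 792 without CD20-positive replicate 1 and 1632 without both libraries of replicate 1. In the paired fit the 954 genes moved to 269 (76 higher, 193 lower) at a mean of at least 50 FPKM, 0 (0 and 0) with no filter, 2452 (51 and 2401) with the FPKM total, 1443 (212 and 1231) with the fragment total, 2361 (1089 and 1272) with weights, 95 (48 and 47) at a fold change of at least 2 and 560 (252 and 308) at adjusted p under 0.01. Leaving out a pair gave 64 to 1212 (39 to 516 higher, 25 to 753 lower); the 64 without replicate 3 included 58 of the 954. Voom with the block called 958, of which 862 were shared with the 954. The prior degrees of freedom of the paired fit were 2.61 with no filter, 10.2 at 1 FPKM (767 genes) and infinite at the median in the main setting; the cause of these moves was not tested. Of the list tests, 10 passed with the preset correlation, 0 with an estimated correlation and 3 with fry. Leaving out 1 library gave from 7 lists (without CD20-negative replicate 2) to 10 (without CD20-positive replicate 3) at the preset correlation. The replicate block ended the camera calls of the lists of stem-like markers and cholesterol synthesis (8 passed at the preset correlation) and the fry calls of the lists of extracellular matrix, stem-like markers and mitochondrially encoded genes (0 passed, smallest adjusted p 0.0924), and changed the calls of 59 named genes. MS4A1 stayed higher and short of the threshold in the settings run, with a log2 change of 0.12 (pseudocount 10) to 1.92 (voom) and adjusted p of 0.0781 to 0.944. For lists, the value followed here is the mean change minus that of the other genes, and it kept its sign in the settings run for the 10 lists past the threshold; scaling by 1 factor per library shifts all genes nearly alike and so cannot test this. The median change itself turned with the FPKM total in 5 of them, G2 and M phase (-0.13), stem-like markers (-0.17), undifferentiated invasive state (-0.18), epithelial-mesenchymal transition (-0.21) and cholesterol synthesis (-0.35), and in the last also with the fragment total (-0.027), and it fell to 0.075 for extracellular matrix and 0.11 for hypoxia response with the FPKM total. With the FPKM total the median of all tested genes was itself -0.50. With the filter at 1 FPKM the paired calls went from 36 of 39 to 19 of 39 for ribosomal proteins, 13 of 13 to 9 of 13 for mitochondrially encoded genes, 26 of 37 to 16 of 43 lower for nuclear-encoded oxidative phosphorylation, 14 of 17 to 8 of 19 for extracellular matrix, 2 of 5 to 0 of 11 for stem-like markers and 4 of 22 to 1 of 25 for cholesterol synthesis. The correction for length and GC content took the nuclear-encoded oxidative phosphorylation genes called lower from 26 to 17. The named genes that changed sign were not called without the block, but TGFBI, MCAM, EPHA2, P4HA1, PDIA4, NFKB2, MVD, MT-ND4, MT-CO3 and EGR1 were called in the paired fit. The sign changed with the FPKM total for CLDN4 (-0.31), KRT19 (-0.23), CDK2 (-0.19), NES (-0.20), TGFBI (-0.047), MCAM (-0.0038), NOTCH1 (-0.17), EPHA2 (-0.016), P4HA1 (-0.089), PFKP (-0.19), RRM1 (-0.17), PDIA4 (-0.021), HSPA5 (-0.14), CEBPB (-0.087), SOCS3 (-0.33), JUND (-0.32), SERPINH1 (-0.12), NFKB2 (-0.058), TNFAIP2 (-0.32), NFKBIA (-0.31), DHCR7 (-0.043), MVD (-0.052), TNFRSF10B (-0.23), GDF15 (-0.27), ABCC2 (-0.30); with the fragment total for SOCS3 (-0.028), TNFAIP2 (-0.0020); with quantile normalisation, which fixes the values of the top ranks that MT-ND4 and MT-CO3 hold, for MT-ND4 (-0.072), MT-CO3 (-0.10), MYC (0.19), the list of immediate-early and dissociation response (0.0018), the list of MAPK pathway output (0.018), the list of nuclear-retained long non-coding RNAs (0.039); with library weights for ANXA1 (0.081), EGR1 (0.20); and at 1 FPKM for the list of MAPK pathway output (0.077). With libraries left out, the sign changed within these ranges: ANXA1 (-0.25 to 0.17), EGR1 (-1.28 to 0.027), the list of S phase (-0.033 to 0.21), the list of immediate-early and dissociation response (-0.25 to 0.13), the list of p53 targets (-0.17 to 0.12), the list of MAPK pathway output (-0.25 to 0.17), MYC (-0.32 to 0.037), GDF15 (-0.043 to 0.44), NRARP (-0.27 to 0.17), the list of nuclear-retained long non-coding RNAs (-0.20 to 0.29), KRT19 (-0.033 to 0.49). Depth limits MS4A1, with 347 fragments in the 6 libraries.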

Other observations

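The tests in this part were chosen after the data were seen; the correction for length and GC content and the splits for the gene lists were set down before the values that these measure were known.

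Genes of replication-dependent histones, many of whose transcripts lack a poly(A) tail, had 3 tested members at a mean of 10 FPKM, too few for the list test. At a mean of 1 FPKM, 12 were tested and 12 of 12 had a negative log2 change, with a median of -0.48 (camera, adjusted p = 5.6e-05; adjusted p = 0.303 with an estimated correlation); 3 were called lower in the paired fit, and 12 when adjusted over the list alone. H2BC5 went from 16.3 ± 5.24 to 8.78 ± 4.96 FPKM in CD20-positive cells. The G2 and M phase list had 18 of 54 higher at that filter, with 49 of 54 positive in sign. The ABC drug transporter list had 8 tested members and 1 called, ABCC3 at 0.57 (camera, adjusted p = 0.0237, and 0.244 with an estimated correlation). The list of WNT, NOTCH and Hedgehog targets had 3 of 13 higher in the paired fit (camera, adjusted p = 0.0181, and 0.244 with an estimated correlation). The melanocytic, neural crest-like and inflammatory NF-kB lists, also tested at this filter, did not pass (camera, adjusted p = 0.566, 0.0743 and 0.0692). Cancer-testis antigens were at or near 0 throughout, with no gene above a mean of 0.0195 FPKM. FOLR1, the folate receptor, was among the highest nuclear genes, at 4584 ± 1507 FPKM in CD20-positive and 3166 ± 1162 in CD20-negative cells (exact permutation test, p = 0.3), and was named after its values were seen.

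The rise of mitochondrially encoded genes and the fall of ribosomal protein genes could come from library chemistry, from scaling or from damaged cells. A trend in transcript length and GC content, fitted per pair on other nuclear genes and explaining 43.2, 14.5 and 22.0% of the variance of the pair changes, was subtracted: the ribosomal protein median then stood at -0.70, with 29 of 39 genes still called lower, and the mitochondrial median at 2.00, with 11 of 13 called higher, which argues against that trend as the whole cause of either. Scaling by 1 factor per library cannot move the ribosomal protein median against that of all genes; quantile normalisation can, and with it the difference was -0.57, which argues against the scaling for these genes. For the mitochondrial genes quantile normalisation decides nothing, since it fixes the values of the top ranks that most of them hold, but their share of the fragments, which no scaling of a library changes, was at least 2.08 times as high in CD20-positive cells in each pair, which argues against the scaling for them as well. Loss of cytosolic RNA from damaged cells, which would raise RNAs kept in the nucleus as well, stays open. The list of nuclear-retained long non-coding RNAs had a median change of -0.15, but it holds NORAD and GAS5, which lie largely in the cytoplasm and both fell. Of its 7 tested members 3 had a positive and 4 a negative change. Among the nuclear ones MALAT1 changed by 0.58 and NEAT1, named after its values were seen, by -0.25. The remaining members were not weighed singly. A difference in mitochondrial content or in ribosome synthesis between the sorted cells, or an effect of the sort, remains open and was not tested.

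Both libraries of replicate 1 stood apart from those of replicates 2 and 3. The chi-square per degree of freedom between CD20-negative libraries was 49.6 and 47.3 for replicate 1 against 2 and 3, and 9.49 between 2 and 3; for the CD20-positive libraries it was 106 and 93.7, and 23.1. Depth was not the difference: the replicate 1 libraries held 17564537 and 17479726 fragments, within the range of the other 4. At that depth they held fewer genes at 1 FPKM or more, 12738 and 12673, against 13211 to 13492 in the other 4. Whether this reflects library quality was not tested. The deviations of the replicate 1 libraries from their group means correlated at 0.73 across genes, which is in line with a difference shared by both fractions of that replicate; whether it came from the culture, the day or the library preparation was not tested.

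Depth was weighed as a source of the low melanocytic and high keratin transcripts of cells labelled as M14. Of the nuclear-encoded oxidative phosphorylation genes 95.6% reached a mean of 1 FPKM, and of the melanocytic genes 33.3% did. These shares cannot decide it, since FPKM is divided by library size and the oxidative phosphorylation genes are abundant (median of their means 41.1 FPKM). Depth did suffice to count a gene at a low level: MS4A1 at 0.225 FPKM had 21 fragments in the CD20-negative library of replicate 1. Cells of another type or line, as a part or the whole of the cultures, may be a source of the keratin transcripts. KRT8 was at 174 FPKM or more in every library, so these transcripts were not confined to a single library or group. Loss of the melanocytic program by the line cannot be told apart from such a source, because no reference profile of the line was compared. The identity of the cells as M14 therefore rests on the labels. HLA-B, named after its values were seen, stood at 3.48 FPKM (168 fragments) in the CD20-positive library of replicate 3 and at 0.0409 FPKM or less in the other 5; whether cells from elsewhere brought it into that library was not tested.

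Chance was weighed with other splits of the libraries, which are too few to give a share under 0.05. Without the block, 1 of 10 splits of the 6 libraries gave as many genes, the real one with 1, and the highest other gave 0. With the block, 1 of the 4 splits that part the 3 pairs gave as many, the real one with 954, and the highest other gave 0. For the list tests with the preset correlation, 1 of 10 splits gave as many lists, the real one with 10, but the highest other gave 9, so a list call at the preset correlation is by itself weak evidence.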
